A study of Homo sapiens with 13 samples.

How the data were processed

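Single-cell RNA-seq libraries were made from fresh transition zone tissue of the prostate of people with benign prostatic hyperplasia, a non-malignant enlargement of the gland. Per the labels, tissue was digested with 5 mg/mL collagenase for 4 h and about 17400 cells were loaded per library on the 10x Genomics Chromium with the 3' kit, version 2 for 6 libraries and version 3 for 7. Cells of the version 2 libraries were sorted for viability and those of the version 3 libraries were not, so kit and sort cannot be told apart. The 13 libraries came from 6 donors, named A to F here, and fall into 7 glandular libraries, 5 stromal libraries and 1 library coded PrPUr, a code the labels do not expand. The specimen type was read from the sample titles together with the series title, and that libraries came from the same donor was inferred from a code shared by their titles. Donors A to D each gave 1 glandular and 1 stromal library, donor E gave 1 glandular and the PrPUr library, and donor F gave 2 glandular libraries, F1 and F2, and 1 stromal library. Kit and sort go with the donor and not with the specimen type. Which instrument sequenced each library is not given.

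The deposited values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 4.0.0 on GRCh38, per the submitters' processing notes. The files held 36601 genes and 118198 barcodes. Of the gene IDs, 34616 were found in GENCODE 29, which gave the coordinates printed with GRCh38 positions. For privacy, 103 genes that depend on the sex chromosomes (Y-linked genes, XIST and TSIX) were left out of every table, and genes that follow common deletions or haplotypes of a person were not named. The total UMI count per library ran from 9569564 to 66026775.

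Barcodes with under 500 UMIs, under 300 genes or over 20% mitochondrial UMIs were left out (4420 barcodes by the first 2 limits and 8508 by the third). Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5 with 30 components. Its automatic threshold called 0% to 6.09% of cells, so the top-scoring cells were removed up to the rate expected from loading, 0.8% per 1000 cells, which was 2.42% to 12.8% per library and 7596 cells in all. The 97674 retained cells had a median of 2069 to 6201 UMIs per library. Counts were scaled per cell and log-transformed, and 2000 variable genes and 40 principal components were used. Each cell was joined to its 5 nearest cells of every donor, and the graph was clustered with the Leiden method at resolution 1 (python-igraph 0.11.9). Clusters with mixed or weak markers and at least 200 cells were clustered again with 1000 genes, 20 components and resolution 0.4. This gave 35 clusters.

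A cluster was named "X-like" from marker lists fixed before the data were examined, if at least 3 markers were detected in 10% of its cells and at least 1 log2 unit above the other clusters, with a prior of 20 CPM. Rules on mixed, shallow and small clusters were set after the clusters had been seen, before any comparison of specimen types. A cluster was called mixed where another list scored at least 0.75 of the best score or led its 10 leading genes, and it stayed unnamed where its depth was below 0.6 of its libraries' median with a mean marker log2 fold below 1.5, or where under 100 cells had no marker among the leading genes. These rules left 6 mixed and 2 unnamed clusters beside 14 named classes. Unnamed cells made up 0.131% to 0.569% of the glandular libraries, 0.247% to 31.4% of the stromal libraries and 0.356% of the PrPUr library. Mixed cells made up 2.09% to 6.50%, 2.80% to 8.26% and 2.62%.

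The numbers of cells per class were compared between stromal and glandular samples of the 5 donors with both types by edgeR 4.0.16's quasi-likelihood test with the donor as a block, beside an exact two-sided sign-flip test over the donor pairs. The epithelial share and the make-up within the epithelial and the stromal and vascular lineages were compared by the exact sign-flip test alone. With 5 pairs its smallest possible p is 0.063. The F1 and F2 libraries were summed, or averaged for the epithelial share. For genes, UMI counts were summed per donor, specimen type and class, and tested with edgeR's quasi-likelihood test (TMM scaling, its own low-count filter, donor block, two-sided) where at least 4 donors had at least 20 cells of the class in both types. This held for 11 classes. The luminal-like, hillock-like and plasma cell-like classes had too few such pairs, and mixed cells were not tested. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. In these tests CPM is the count of a gene scaled to the TMM-adjusted UMI total of the tested genes of the class in a sample. Elsewhere, as for the PrPUr library, CPM is scaled to all UMIs of the class. Standard errors were derived from edgeR's log2 fold change and its F statistic. Because the fit pairs samples by donor, p-values measure a difference between specimen types against its variation from donor to donor.

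Whether the shared codes paired the samples was checked before calls were compared. In 5 classes the deviations of the stromal and glandular sample of a donor correlated at 0.470 to 0.863 across genes, and those of different donors at 0.292 at most. Replicate libraries of a type differed far beyond sampling noise, with a chi-square per degree of freedom of 66.6 to 726, and of 132 between F1 and F2, so no library was taken for a copy of another.

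Genes named in the text were chosen by a rule fixed before the data were examined. In each class the rule took the 10 genes with the largest log2 fold change in each direction among called genes that moved the same way in every pair and reached a mean of 20 CPM in a specimen type. It added called members of the fixed lists, at most 3 per list where over 30 genes would be named, and APOD and C7 in fibroblast-like cells. Where fewer than 10 genes were called, the 5 with the smallest p were added. A gene was termed free-RNA-prone in a class if its CPM over all libraries was at least 10 times higher in another class, since droplets hold free RNA of lysed cells. The 17 lists were matrix, contractile apparatus, androgen response, TGF-beta and BMP signalling, WNT signalling, growth factors, chemokines and cytokines, interferon response, class II antigen presentation, dissociation stress, hypoxia and glycolysis, metallothionein, steroid metabolism and receptors, cell cycle, ribosomal proteins, mitochondrial transcripts and prostatic secretion, and the markers of the other classes were tested as well. Lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with p-values adjusted over all 230 combinations of list and class, and again with an estimated correlation.

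The PrPUr library had no replicate. It was set beside the glandular library of the same donor with no test, giving exact 95% intervals (binomial for shares, Poisson for counts) that cover counting error only, as do all intervals on shares of single libraries. Genes were named there by size, as the 10 with the largest fold of at least 4 among genes with at least 200 UMIs in the higher library, in classes with at least 50 cells in both. For a class with 0 cells, the upper limit given is 3 cells of the total. Folds against 0 UMIs were computed against a floor of 3 UMIs per library.

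The procedures were tested on simulated data. With counts drawn from the fibroblast-like sums for 13915 genes, 94.0% of genes changed 2-fold and 100% of those changed 4-fold were called, and 6.28% of the calls were false. With the T cell-like sums for 7058 genes these values were 97.0%, 100% and 5.29%. The changed genes were drawn only from those with a mean of at least 20 CPM. Each gene was drawn independently with the spread that edgeR had estimated. These values therefore do not give the power for lower genes or the error rate in the real data. Shares lowered 8-fold were called in 39 of 40 cases, beside 3 of 280 unchanged classes. The spread between samples was fixed for this simulation and not estimated from the data, so it does not give the power of the real test. In the real data the plasma cell-like share did not pass at a log2 fold change of -3.17 (edgeR adjusted p = 0.124). Camera called 12 of 259 lists with the fibroblast-like sums and 7 of 203 with the T cell-like sums in data without change. These calls were counted after adjustment within each of 10 runs, so they are not an unadjusted error rate. Each gene was drawn independently, so the runs cannot show how camera behaves at the preset correlation when genes are correlated. With the contractile list alone shifted, camera called it with both sums, and also called 6 others of 26 lists with the fibroblast-like sums and 0 others of 19 with the T cell-like sums.

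Alternatives were predicted doublets kept, a mitochondrial ceiling of 10%, a doubled resolution, an ordinary neighbour graph of 30 neighbours, each donor left out, no donor block, kit as a covariate, DESeq2 1.42.0, DESeq2's size factors, no filter on low counts, free-RNA-prone genes left out, pairs of kit version 2 alone, a minimum of 50 cells, and for shares TMM scaling and the sign-flip test. Leaving out unnamed cells, leaving out cells under 1500 UMIs, and using F1 or F2 alone were added after the data had been seen. Python 3.11.15 and R 4.3.3 were used.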

Results

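Transcripts were counted in single cells of 13 libraries of human prostate transition zone tissue with benign hyperplasia, of which 7 were glandular, 5 stromal and 1 coded PrPUr. The glandular libraries of donors A to E held 31066596, 29058399, 54270891, 49544164 and 63333600 UMIs, and the F1 and F2 glandular libraries of donor F held 54465348 and 49863031. The stromal libraries of donors A, B, C, D and F held 9569564, 35351194, 41912328, 66026775 and 51539330 UMIs, and the PrPUr library of donor E held 59313878. From 2953 to 14027 cells per library were retained, at a median of 2069 to 6201 UMIs. The median depth was lower in the stromal library of donor A, where 31.4% of cells stayed unnamed, than in any other library. Each comparison below sets stromal against glandular samples of the 5 donors with both types, the specimen types named in the series title, and asks which cell classes and transcripts differ between them. Positive log2 values are higher in stromal samples.

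Epithelial-like cells made up 40.5% ± 26.4 of the cells in glandular samples and 8.03% ± 12.5 in stromal samples (SD, n = 5 donors), a difference of -32.5 percentage points ± 18.9. The share was lower in the stromal sample of 5 of 5 donors (exact two-sided sign-flip p = 0.063, the smallest that 5 pairs allow). The mean difference was -43.3 points in the 3 pairs of kit version 2 and -16.3 points in the 2 pairs of version 3. Among the single classes, luminal epithelial-like cells, the secretory cells of the gland, went from 2.83% ± 1.70 in glandular samples to 0.181% ± 0.142 in stromal samples (edgeR log2 fold change -4.36 ± 1.03 SE, adjusted p = 0.0113). Basal epithelial-like cells, which line the gland's outer layer, went from 28.0% ± 21.8 to 6.57% ± 11.3 (log2 -4.00 ± 1.19, adjusted p = 0.0316). Club epithelial-like cells, named for secretoglobins such as SCGB3A1, went from 6.56% ± 5.93 to 0.926% ± 1.22 (log2 -3.49 ± 0.84, adjusted p = 0.0113). Each of these 3 classes was lower in 5 of 5 stromal samples, with mean log2 ratios of -3.62, -2.84 and -3.12 in kit version 2 and -6.16, -6.14 and -4.52 in version 3. Fibroblast-like cells were 7.36% ± 5.85 and 18.6% ± 11.4 (higher in 4 of 5 stromal samples, adjusted p = 0.267) and vascular endothelial-like cells 10.2% ± 8.54 and 17.7% ± 11.9 (4 of 5, adjusted p = 0.267). Smooth muscle-like cells were 2.46% ± 1.74 and 3.98% ± 1.86 (5 of 5, adjusted p = 0.365). None of these 3 passed. The vascular endothelial-like share leaves out a shallow unnamed cluster whose best marker list was vascular endothelial (mean log2 fold 1.05). That cluster held 927 cells of stromal A, where 31.4% of cells stayed unnamed, and 13 cells of glandular A. Its cells could be endothelial, and the share was not tested with them counted in. The shares within lineages below leave them out as well. Plasma cell-like cells were 0.646% ± 0.689 and 0.0706% ± 0.0768 (lower in 4 of 5, adjusted p = 0.124), and the other 9 classes also stayed above the threshold. In the hillock epithelial-like class, KRT13-expressing cells, the stromal share was lower with kit version 2 (mean log2 ratio -5.43) and higher with version 3 (1.25), and this difference between kits passed its test (adjusted p = 0.00797). Of the 16 classes tested, 3 passed with 5 donors, 0 without donor B, 2 without donor D, 1 without the donor block, and 0 in the exact sign-flip test, which cannot reach the threshold with 5 pairs.

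**Figure D1:**
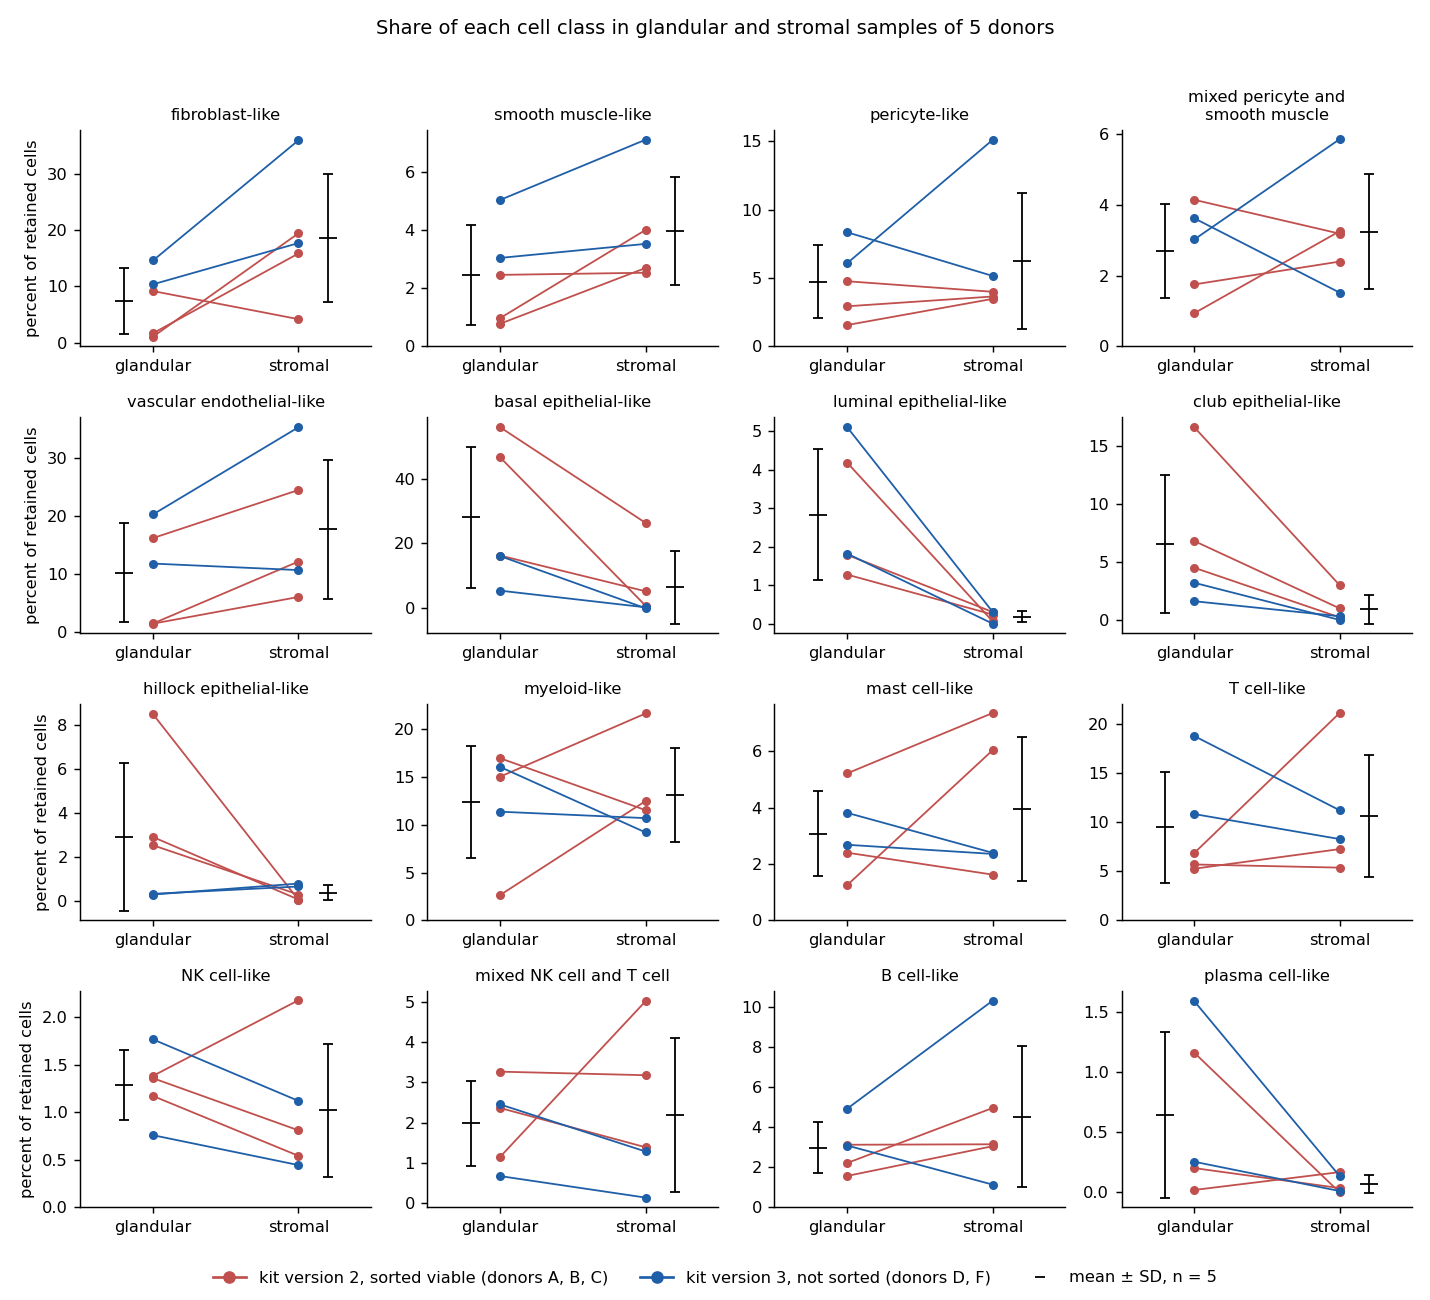
Each panel gives the percent of retained cells in a cell class (vertical axis) in the glandular and stromal sample of each of 5 donors, joined by a line coloured by kit version, with the mean ± SD of each specimen type in black. Basal, luminal and club epithelial-like shares fell from the glandular to the stromal sample in 5 of 5 donors, while hillock epithelial-like shares moved in opposite directions in the pairs of the 2 kits.

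Within lineages, luminal epithelial-like cells were 13.3% ± 15.9 of the epithelial-like cells in glandular samples and 5.44% ± 7.0 in stromal samples (lower in 5 of 5, exact sign-flip p = 0.063, adjusted p = 0.422). Basal epithelial-like cells were 63.8% ± 16.0 and 52.8% ± 37.4 of that lineage. Among stromal and vascular cells, fibroblast-like cells were 24.0% ± 6.75 and 38.1% ± 20.9, and pericyte-like cells, which wrap small vessels, were 21.8% ± 11.2 and 11.6% ± 4.48. The mean change of the fibroblast-like share was 15.3 points with kit version 2 and 12.1 with version 3, and that of the pericyte-like share -15.0 and -2.90 points. The exact two-sided sign-flip test called 0 of 9 lineage shares, and 0 had an unadjusted p under 0.05, which 5 pairs cannot give. No test that could pass with 5 pairs was run within lineages.

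Stromal fibroblast-like cells held more PI16, a peptidase inhibitor typical of adventitial fibroblasts, with 113 CPM against 19.5 CPM in glandular ones (log2 fold change 3.25 ± 0.43 SE, adjusted p = 0.00758). PI16 (ENSG00000164530) lies on chromosome 6 at 36948263 to 36964837. They also held more BAMBI, a decoy receptor of TGF-beta and BMP signalling (1.41 ± 0.18), and SLIT3, a secreted guidance cue (1.31 ± 0.17). NCAM1, a cell adhesion molecule (1.16 ± 0.17), and SGCA, a part of the sarcoglycan complex (1.67 ± 0.33), were also higher, with PITX1, SCRG1 and CADPS between 1.32 and 2.12. Glandular fibroblast-like cells held more of GPC3, a cell-surface proteoglycan (-1.97 ± 0.28), FAP, a protease of activated fibroblasts (-1.71 ± 0.26), PCDH7, a protocadherin (-2.34 ± 0.32), and LIF, a cytokine of the interleukin-6 family (-1.10 ± 0.23, adjusted p = 0.0454). CCL19, a lymphocyte-attracting chemokine on chromosome 9 at 34689567 to 34691277, was also lower in stromal samples (-2.76 ± 0.27, 80.6 to 11 CPM), but was over 10 times higher in another class, as was AREG, an EGF receptor ligand (-1.68 ± 0.18). The complement gene C7 (-0.04 ± 0.17, adjusted p = 0.999) and the lipocalin APOD (-0.68 ± 0.27, adjusted p = 0.353) did not pass. Of 13915 genes tested with 5 pairs, 60 were higher and 51 lower (1463 at an unadjusted p under 0.05), and 47 and 37 of these were not free-RNA-prone, that is, not 10 times higher in another class. Cells of cluster 1, led by CFD and PTGDS, made up 53.5% ± 13.1 of the class in glandular and 50% ± 28.4 in stromal samples, and those of cluster 5, led by FBLN1 and IGF1, 46.5% ± 13.1 and 50% ± 28.4. The prone ones included epithelial keratins and secretory transcripts such as KRT15 (-2.86 ± 0.37) and MSMB (-3.99 ± 0.77), which were lower in stromal samples. The mean log2 ratios of PI16 were 2.46 with kit version 2 and 4.19 with version 3, and those of GPC3 -1.56 and -2.38. The count was 244 without donor A, 18 without B, 25 without D, 56 without F, 13 in the pairs of kit version 2 alone and 1 without the donor block.

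In smooth muscle-like cells, matrix transcripts were lower in stromal samples, with a median log2 fold change of -0.45 over 16 list members (camera adjusted p = 1.28e-08, and adjusted p = 0.125 with an estimated correlation). Of these members 3 passed over all genes, and 7 were lower when adjusted over the list alone. They were the collagen COL3A1 (-0.94 ± 0.16 SE) and the proteoglycans DCN (-1.14 ± 0.21) and LUM (-1.53 ± 0.26), and LUM was free-RNA-prone. DCN and LUM are also fibroblast markers, a list that was lower here, with a median of -0.66 over 5 members (camera adjusted p = 8.87e-10, and adjusted p = 0.125 with an estimated correlation), 4 of them when adjusted over the list alone. Cluster 2.0, led by ALKAL2, STEAP4 and MT1A, made up 97.5% ± 2.91 of the class in glandular and 95.1% ± 4.85 in stromal samples. The rest, cluster 2.4, was led by DES and ACTG2. ALKAL2, CCL19 and GJA4 were among the 10 leading genes of both cluster 2.0 and the pericyte-like cluster 2.1, so the line between these classes was not sharp. Contractile transcripts were higher as a list, with a median of 0.41 over 14 members (camera adjusted p = 2.95e-05, and adjusted p = 0.453 with an estimated correlation), although 0 members passed singly in edgeR and 0 when adjusted over the list alone. Single genes lower in stromal samples were SFRP1, a secreted WNT antagonist on chromosome 8 at 41261958 to 41309497 (-2.38 ± 0.51, lower in 4 of 5 pairs, adjusted p = 0.0392), and FZD10, a WNT receptor (-1.45 ± 0.31). So were CYP1B1, a cytochrome that hydroxylates estrogens (-1.53 ± 0.25), INHBA, an activin subunit (-1.22 ± 0.22), and CCL19 (-1.50 ± 0.30, 1435 to 410 CPM). RRAS, a small GTPase (0.82 ± 0.18), and TPD52L1 (1.63 ± 0.32) were higher. Of 6302 genes tested, 3 were higher and 30 lower (664 at an unadjusted p under 0.05), of which 2 and 21 were not free-RNA-prone. MSMB was lower here too (-3.98 ± 0.41). DCN had mean log2 ratios of -1.59 with kit version 2 and -0.49 with version 3, and CYP1B1 of -1.95 and -0.87. The count of 33 was 19 without donor C, 18 without D, 14 without F, 6 in the pairs of kit version 2 alone and 0 without the donor block. It was 8 with an ordinary neighbour graph, of which 5 were among the 33, 80 with a doubled resolution and 60 with predicted doublets kept.

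Pericyte-like cells of stromal samples held more ELN, which encodes elastin (1.83 ± 0.29 SE, 8.30 to 35.7 CPM, adjusted p = 0.0170, chromosome 7 at 74027789 to 74069907), and MFAP4, a microfibril protein (1.30 ± 0.17). The matrix list was not called here, with a median of -0.10 over 16 members (camera adjusted p = 0.338, and adjusted p = 0.787 with an estimated correlation). Contractile transcripts were higher as a list, with a median of 0.21 over 14 members (camera adjusted p = 0.000151, and adjusted p = 0.396 with an estimated correlation). Among them CNN1, an actin-binding calponin (0.93 ± 0.20), and MYH11, the smooth muscle myosin heavy chain (0.59 ± 0.13), passed over all genes, and 4 were higher when adjusted over the list alone. Both are also smooth muscle markers, a list that was higher here, with a median of 0.52 over 6 members (camera adjusted p = 9.59e-05, and adjusted p = 0.279 with an estimated correlation). The class pools cluster 2.1, led by RGS5 and NDUFA4L2, with 59.0% ± 25.2 of it in glandular and 47.0% ± 24.9 in stromal samples (lower in 5 of 5), cluster 2.2, led by RGS16 and DEPP1 (40.5% ± 25.2 and 44.9% ± 21.6), and cluster 2.5 (0.509% ± 0.581 and 8.13% ± 12.1). Smooth muscle markers had a mean log2 fold of 1.78 in cluster 2.2 and 0.627 in cluster 2.1. CXCL12, a chemokine of stromal cells (1.12 ± 0.18), NTRK2, a neurotrophin receptor (1.57 ± 0.27), and IGFBP5, an IGF-binding protein (1.01 ± 0.21), were also higher. Lower in stromal samples were EGFL6, an EGF-like matrix protein (-2.00 ± 0.37), PDE8B, a cAMP phosphodiesterase (-1.54 ± 0.19), CXCL1, a neutrophil-attracting chemokine (-1.47 ± 0.21), CYP1B1 (-1.10 ± 0.18) and the metallothioneins MT2A (-0.80 ± 0.15) and MT1E (-1.25 ± 0.25). Of 7806 genes tested, 40 were higher and 43 lower (894 at an unadjusted p under 0.05), of which 32 and 32 were not free-RNA-prone. Markers of endothelial cells such as VWF (2.03 ± 0.44) and SELE (3.10 ± 0.25) rose and epithelial transcripts such as MSMB (-3.58 ± 0.59) fell in the same samples, all of them free-RNA-prone. For ELN the mean log2 ratios were 2.32 with kit version 2 and 1.65 with version 3. The count of 83 was 21 without donor C, 32 without D, 41 without F, 27 in the pairs of kit version 2 alone and 0 without the donor block.

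**Figure D2:**
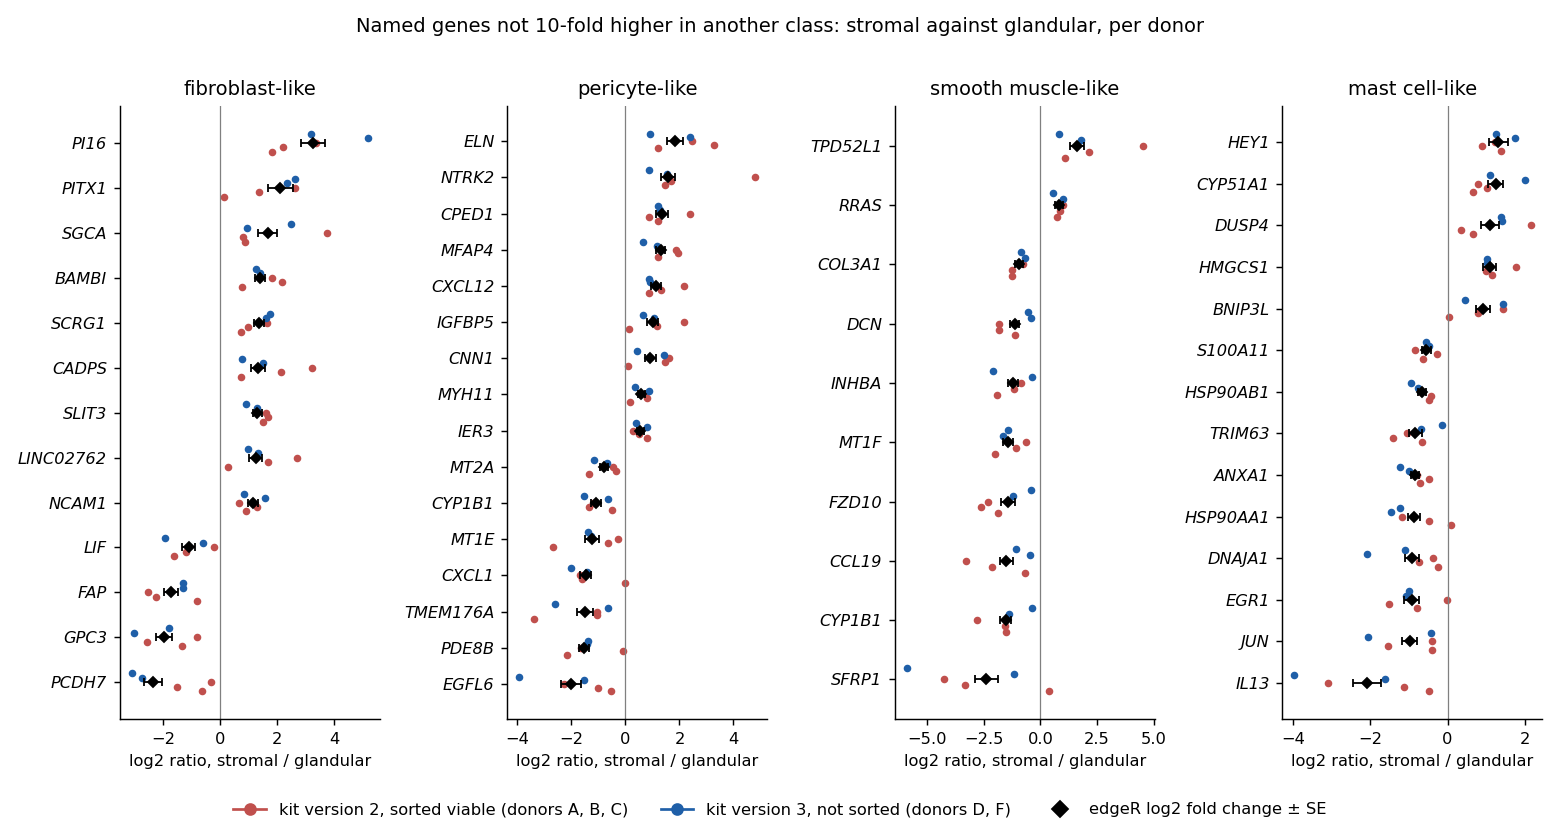
Points give the log2 ratio of stromal to glandular CPM (horizontal axis, with 1 CPM added to each) per donor, coloured by kit version, and diamonds edgeR's log2 fold change ± SE, for the named genes that passed and were not 10 times higher in another class, in 4 cell classes. PI16 in fibroblast-like cells and ELN in pericyte-like cells lay right of 0 and GPC3 in fibroblast-like cells and IL13 in mast cell-like cells left of 0 in 5 of 5 donors.

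Vascular endothelial-like cells of stromal samples showed higher chemokine and cytokine transcripts, with a median log2 fold change of 0.93 over 19 list members (camera adjusted p = 1.72e-24, and adjusted p = 0.125 with an estimated correlation). Of the members, 14 were higher and 1 lower when adjusted over the list alone, while over all genes CCL4, a macrophage chemokine (1.74 ± 0.26 SE), was higher and CXCL12 (-1.39 ± 0.25) lower, both free-RNA-prone. Fibroblast markers were higher too, with a median of 0.97 over 6 members (camera adjusted p = 8.27e-10, and adjusted p = 0.156 with an estimated correlation), 5 of them when adjusted over the list alone. Smooth muscle markers had a median of 0.94 over 3 members (camera adjusted p = 0.00468, and adjusted p = 0.305 with an estimated correlation). This class also pools clusters, of which cluster 3, led by SELE and CSF3, held 47.8% ± 18.5 of it in glandular and 56.7% ± 15 in stromal samples, and cluster 9, led by ESM1 and STC1, 34.9% ± 23.7 and 25.5% ± 12.2. CCL21, the chemokine of lymphatic vessels, was higher (2.77 ± 0.41), from 1.96 to 28.5 CPM, and was free-RNA-prone as well. Not prone among the named genes were LINC01235, a non-coding RNA (-2.35 ± 0.33, adjusted p = 0.0111), and CCDC3, a secreted protein (-1.03 ± 0.18, adjusted p = 0.0372), both lower. Of 11683 genes tested, 5 were higher and 13 lower (818 at an unadjusted p under 0.05), and 0 and 4 of these were not prone. MSMB (-4.10 ± 0.48) and KRT14 (-3.09 ± 0.47), transcripts of luminal and basal cells, were lower in the stromal samples. The mean log2 ratios of LINC01235 were -1.99 in kit version 2 and -2.20 in version 3. The count of 18 was 85 without donor A, 5 without B, 11 without C, 43 without F, 44 in the pairs of kit version 2, 49 with DESeq2 and 0 without the donor block.

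Basal epithelial-like cells of stromal samples held less KLK3 (-3.31 ± 0.35 SE, adjusted p = 0.00359) and KLK2 (-3.06 ± 0.43), kallikreins secreted by luminal cells, less SERPINB3, a protease inhibitor (-3.98 ± 0.43), and less MT1G, a metallothionein (-1.83 ± 0.27). They held more DUSP2, a MAP kinase phosphatase (1.64 ± 0.21), and GADD45G, a stress-induced regulator (1.90 ± 0.26). All of these were free-RNA-prone, while ARHGAP29-AS1, an antisense RNA that was lower (-2.11 ± 0.27, adjusted p = 0.0127), was not. Of 11583 genes tested in 4 pairs, 4 were higher and 5 lower (786 at an unadjusted p under 0.05). ARHGAP29-AS1 had mean log2 ratios of -1.77 with kit version 2 and -2.43 with version 3, which held 1 pair here. The count of 9 was 32 without donor A, 5 without C, 4 without D, 42 with DESeq2 and 0 without the donor block. In club epithelial-like cells, the smallest p-values belonged to C1R, a complement protease (-1.59 ± 0.21, adjusted p = 0.418), and MSMB (-3.43 ± 0.50, adjusted p = 0.429). Next came MT2A, SAA2 and SPARCL1 (-1.68, -2.46 and 2.51, adjusted p = 0.777). edgeR called 0 of 9216 genes there in 4 pairs, with 180 at an unadjusted p under 0.05 and 10 called by DESeq2. Its count was 1 without donor A, 0 without B, 0 without C and 35 without D.

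Myeloid-like cells of stromal samples held less CCL18, a chemokine of alternatively activated macrophages (-1.90 ± 0.24 SE, adjusted p = 0.00790), and GPNMB, a glycoprotein of lipid-laden macrophages (-1.42 ± 0.27). They also held less VCAN, a proteoglycan of monocytes (-1.40 ± 0.21), and S100B, a calcium-binding protein (-1.78 ± 0.30). Class II antigen presentation transcripts were lower as a list, with a median of -0.27 over 8 members (camera adjusted p = 0.0111, and adjusted p = 0.309 with an estimated correlation), with 0 members passing singly in edgeR. Cell cycle transcripts were also lower as a list, with a median of -0.35 over 13 members (camera adjusted p = 6.25e-06, and adjusted p = 0.175 with an estimated correlation). Of these, 0 passed over all genes in edgeR and 5 were lower when adjusted over the list alone. Of 11390 genes tested, 35 were higher and 32 lower (1664 at an unadjusted p under 0.05), but 3 and 14 were not free-RNA-prone. The prone genes that were higher included transcripts of vessels, pericytes and fibroblasts such as SELE (3.14 ± 0.30), RGS5 (2.04 ± 0.38) and DCN (1.87 ± 0.34), and those lower included MSMB (-3.59 ± 0.56) and KRT15 (-3.26 ± 0.36). CCL18 had mean log2 ratios of -1.76 with kit version 2 and -1.78 with version 3. The count of 67 was 17 without donor B, 33 without D, 16 in the pairs of kit version 2, 131 with DESeq2 and 0 without the donor block.

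Mast cell-like cells of stromal samples held less IL13, a type 2 cytokine on chromosome 5 at 132656263 to 132661110 (-2.09 ± 0.35 SE, 109 to 36.8 CPM, adjusted p = 0.00671). ANXA1, an anti-inflammatory annexin, was also lower (-0.85 ± 0.10, 7023 to 3792 CPM, adjusted p = 0.000535). Dissociation stress transcripts were lower as a list, with a median of -0.57 over 19 members (camera adjusted p = 1.44e-13, and adjusted p = 0.156 with an estimated correlation). The transcription factors JUN (-0.98 ± 0.20) and EGR1 (-0.93 ± 0.19) and the chaperone HSP90AA1 (-0.86 ± 0.16, lower in 4 of 5 pairs) passed over all genes, and 12 members were lower and 1 higher when adjusted over the list alone. The chaperones HSP90AB1 (-0.66 ± 0.10) and DNAJA1 (-0.92 ± 0.19) were lower too. Higher in stromal samples were HMGCS1 (1.10 ± 0.17) and CYP51A1 (1.25 ± 0.20), enzymes of cholesterol synthesis, HEY1, a Notch target (1.31 ± 0.24), DUSP4, a MAP kinase phosphatase (1.11 ± 0.24), and BNIP3L, a mitophagy receptor (0.92 ± 0.18). Of 5089 genes tested, 18 were higher and 15 lower (392 at an unadjusted p under 0.05), of which 9 and 11 were not free-RNA-prone, while MSMB (-3.78 ± 0.47) was prone and lower. IL13 had mean log2 ratios of -1.57 with kit version 2 and -2.80 with version 3. The count of 33 was 72 without donor A, 16 without B, 21 without C, 20 without F, 17 in the pairs of kit version 2, 21 with DESeq2 and 1 without the donor block.

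T cell-like cells of stromal samples held less CCL20, the ligand of CCR6 on chromosome 2 at 227805739 to 227817564 (-2.03 ± 0.17 SE, 452 to 103 CPM, adjusted p = 4.28e-05). They also held less PMCH, a neuropeptide precursor (-2.26 ± 0.49), and less of the metallothioneins MT1E (-2.04 ± 0.24) and MT1F (-2.03 ± 0.21). Ribosomal protein transcripts were lower as a list, with a median of -0.29 over 15 members (camera adjusted p = 4.34e-06, and adjusted p = 0.452 with an estimated correlation). Of these, 0 passed over all genes in edgeR and 12 were lower when adjusted over the list alone. Mitochondrial transcripts were lower as well, with a median of -0.22 over 10 members (camera adjusted p = 0.0292, and adjusted p = 0.657 with an estimated correlation). These values pool unlike T cell clusters, since 61.1% ± 14.1 of the class in glandular samples lay in cluster 8, led by IL7R, KLRB1 and LTB, and 67.0% ± 15.7 in stromal samples in cluster 7, led by GZMK, CCL5 and NKG7. Of 7058 genes tested, 46 were higher and 72 lower (860 at an unadjusted p under 0.05), and 14 and 53 were not free-RNA-prone. The prone genes included fibroblast transcripts such as DCN (1.99 ± 0.39), which were higher, and MSMB (-3.46 ± 0.60), which was lower. CCL20 had mean log2 ratios of -1.95 with kit version 2 and -1.93 with version 3. The count of 118 was 183 without donor A, 23 without B, 70 without D, 36 in the pairs of kit version 2 and 0 without the donor block.

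NK cell-like cells of stromal samples held less IFNG, the type II interferon (-1.48 ± 0.23 SE, 975 to 321 CPM, adjusted p = 0.00171). They also held less SLC5A3, a myo-inositol transporter (-1.42 ± 0.28), and less of the heat-induced genes ZFAND2A (-1.38 ± 0.28) and HSPB1 (-0.74 ± 0.15). These 4 were the called genes of this class that were not free-RNA-prone, out of 6 higher and 7 lower among 2696 genes tested in 4 pairs (159 at an unadjusted p under 0.05). In B cell-like cells, 16 genes were higher and 3 lower among 4371 tested (259 at an unadjusted p under 0.05), and 0 of the 19 called by edgeR were not prone. They included the fibroblast transcript DCN (2.32 ± 0.40), which was higher, and the luminal transcript MSMB (-3.0 ± 0.50), which was lower. IFNG had mean log2 ratios of -1.0 with kit version 2 and -1.84 with version 3. The NK cell-like count of 13 was 1 without donor B, 41 without C, 5 without D, 8 with DESeq2 and 0 without the donor block. The B cell-like count of 19 was 31 without donor A, 5 without B, 7 without D, 50 in the pairs of kit version 2, 15 with DESeq2 and 0 without the donor block.

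Across classes, metallothioneins, which bind zinc and copper, were lower in stromal samples in 7 of the 11 classes tested. Their median log2 fold change was -0.63 in fibroblast-like, -0.74 in smooth muscle-like, -0.80 in pericyte-like, -0.69 in basal epithelial-like, -1.86 in club epithelial-like, -1.23 in myeloid-like and -1.26 in T cell-like cells. With an estimated correlation, adjusted p ranged from 0.156 to 0.279 in these classes. Adjusted over the list alone, 2 of 7 members were lower in fibroblast-like, 5 in smooth muscle-like and 6 in pericyte-like cells. In basal epithelial-like, club epithelial-like and myeloid-like cells 6, 5 and 6 were lower, and 1 was higher in each. MT1A went the other way, with 1.45 ± 0.17 SE in myeloid-like and 2.04 ± 0.27 in T cell-like cells, and was free-RNA-prone in both. Of the members that passed and were lower, 7 of 12 were prone as well, namely MT1E, MT1X and MT1G in myeloid-like, MT1G in smooth muscle-like and basal epithelial-like, and MT2A and MT1X in T cell-like cells. The list call held without prone genes in the 5 classes where it could be tested again, and could not be tested so in myeloid-like and T cell-like cells. Reads shared between near-identical copies leave the values of single members uncertain. Androgen response genes were lower in 10 of 11 classes (lowest adjusted p = 0.125 with an estimated correlation). The called members included KLK3, KLK2 and MSMB, which are luminal secretory genes and free-RNA-prone outside luminal cells, and 0 of the 8 calls that could be tested again held without prone genes. In B cell-like cells the list's median was 0.14, while its mean of -0.61 and its test were lower. Prostatic secretion genes were lower in 8 of 8 classes (lowest adjusted p = 0.125 with an estimated correlation), and the 1 call that could be tested again without prone genes, in club epithelial-like cells, held. Dissociation stress genes were lower in 6 classes, among them T cell-like (median -0.45, adjusted p = 3.96e-05, and adjusted p = 0.472 with an estimated correlation), and higher in 1. Of these 7 calls 6 held without prone genes, and 0 with an estimated correlation (lowest adjusted p = 0.156). Mitochondrial transcripts were lower in 4 classes, where 4 calls held without prone genes and 0 with an estimated correlation (adjusted p = 0.346 to 0.657). Lower in 1 class were steroid metabolism and receptor genes, in pericyte-like cells (median -0.18, adjusted p = 0.00143, and adjusted p = 0.219 with an estimated correlation), where CYP1B1 passed singly.

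Lists that were higher in stromal samples were contractile apparatus (7 of 10 classes), interferon response (7 of 11), growth factors (6 of 11), chemokines and cytokines (5 of 11) and TGF-beta and BMP signalling (4 of 11). Matrix genes were higher in 6 of 9 classes and lower in 2, smooth muscle-like and fibroblast-like cells. With an estimated correlation 0 of these calls passed (lowest adjusted p = 0.125). Of the calls that could be tested again without free-RNA-prone genes, 2 of 2, 1 of 7, 1 of 4, 2 of 4, 2 of 4 and 2 of 3 held in the same direction, in the order given. The 2 matrix calls that held were the lower ones, in smooth muscle-like and fibroblast-like cells. The higher matrix call tested again, in vascular endothelial-like cells, did not hold (camera adjusted p = 0.960). The chemokine and cytokine list of basal epithelial-like cells turned lower without them (adjusted p = 0.0126). Class II antigen presentation, cell cycle and ribosomal protein genes were each lower in 1 of 11 classes, and WNT signalling (8 classes) and hypoxia and glycolysis genes (11 classes) were called in 0 by camera, with lowest adjusted p = 0.0622 and 0.0943. Markers of other classes were tested in each class as well. With an estimated correlation 0 of the calls below passed (lowest adjusted p = 0.125). Luminal epithelial markers were lower in 8 of 8 classes, basal epithelial in 5 of 6, club epithelial in 2 of 4 and hillock epithelial in 1 of 4. Fibroblast markers were higher in 7 of 9 and lower in 2, smooth muscle markers higher in 4 of 5, vascular endothelial in 2 of 2 and myeloid in 1 of 6. Pericyte (3 classes), plasma cell (2), lymphatic endothelial, mast cell, neuroendocrine and T cell markers (1 each) were called in 0 by camera, with lowest adjusted p = 0.237, 0.412, 0.577, 0.114, 0.639 and 0.375. Markers of NK cells, B cells, urothelial umbrella cells, Schwann glia and erythrocytes had under 3 measured members in every class and were not tested. In all, camera called 109 of 230 combinations of list and class, 50 higher and 59 lower. With an estimated correlation 0 were called, with 57 at an unadjusted p under 0.05 and a lowest adjusted p = 0.125. Without free-RNA-prone genes, 32 of the 55 calls that could be tested again held in the same direction.

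**Figure D3:**
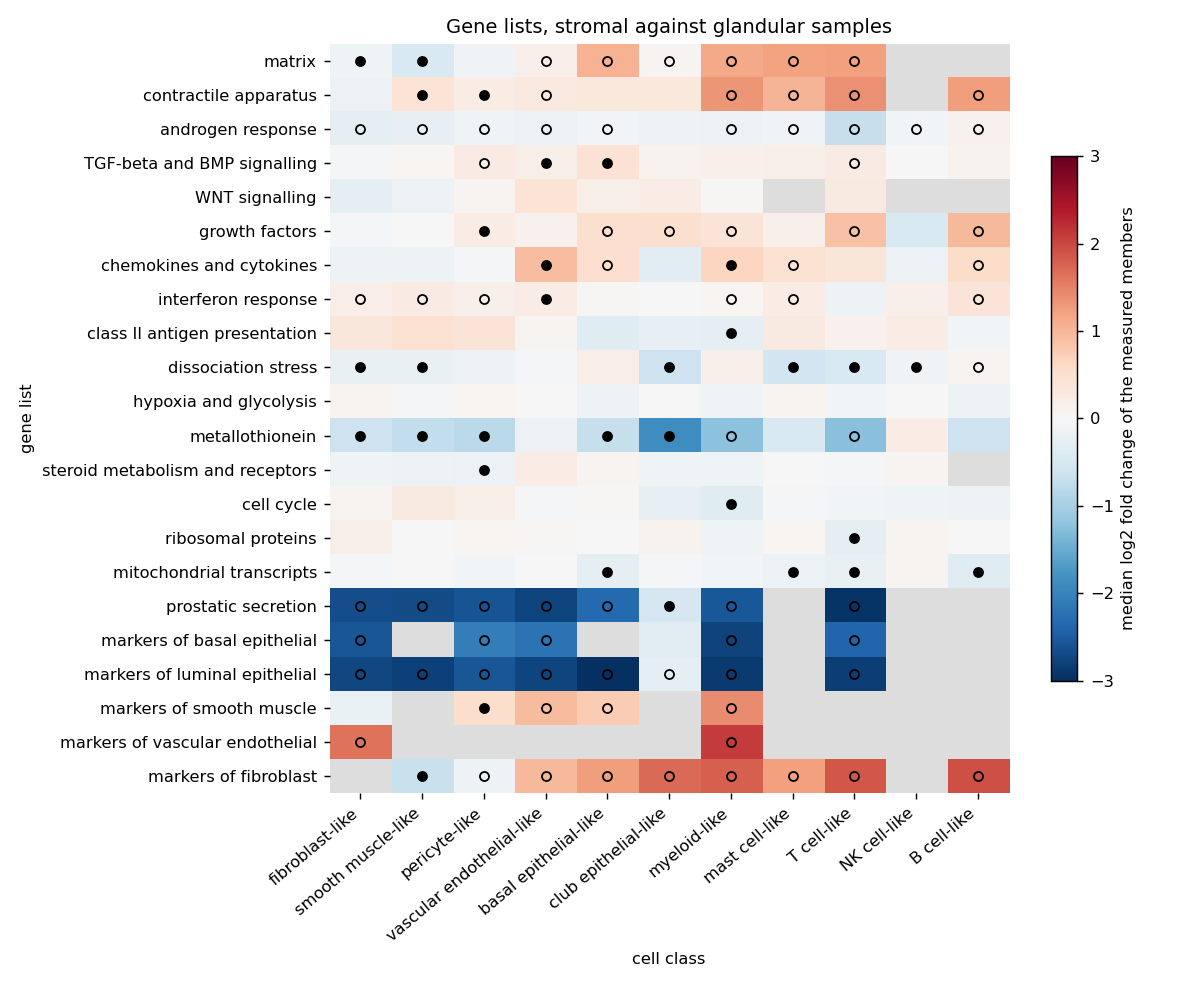
Colours give the median log2 fold change of stromal over glandular samples (scale bar) for each gene list (vertical axis) and cell class (horizontal axis), with grey for combinations not tested and circles for those called by camera at the preset correlation, filled where the call held in the same direction without free-RNA-prone genes. Luminal markers were lower in 8 classes and metallothioneins in 7 at the preset correlation, while 0 lists passed with an estimated correlation (lowest adjusted p = 0.125).

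The effect of specimen type differed between the kits in 36 gene and class combinations by edgeR's interaction test. In B cell-like cells 22 genes differed, among them heat shock genes such as HSPA6 (mean log2 ratio 2.55 with kit version 2 and -1.35 with version 3) and DNAJB1 (0.86 and -0.78). Others were the co-chaperone BAG3 (1.46 and -0.37) and HSPA1A (0.69 and -1.10), whose reads are shared with its near-identical copy HSPA1B. HSPA1A also differed in mast cell-like cells (-0.34 and -2.04) and NK cell-like cells (0.00 and -1.30). In vascular endothelial-like cells 7 genes differed, including HMOX1, which degrades heme (2.27 and -1.52), PTGDS, a prostaglandin synthase (-0.35 and 1.93), and SPP1, the matrix protein osteopontin (-1.82 and -5.71). PTGDS also differed in smooth muscle-like cells (-1.95 and 1.88), with WFDC1, a protease inhibitor of prostate stroma (-1.20 and 1.5). STC1, a secreted glycoprotein, was the 1 such gene in fibroblast-like cells (-3.25 and 1.18), and HEXD-IT1 that in myeloid-like cells (1.68 and -3.58). In pericyte-like and T cell-like cells edgeR called 0, with 387 and 344 genes at an unadjusted p under 0.05. Kit version also parted sorted from unsorted cells and donors A to C from D and F, so the difference cannot be assigned to any of these.

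The PrPUr library was set beside the glandular library of the same donor, with 1 library each and no replicates. Hillock epithelial-like cells made up 9.33% of its cells (exact 95% interval 8.70% to 10.0%), against 0.557% (0.427% to 0.713%) in the glandular library, while club epithelial-like cells were 12.4% and 11.8%. Basal epithelial-like cells were 5.57% (5.07% to 6.10%) against 23.2% (22.4% to 24.0%), and luminal epithelial-like cells 2.07% (1.77% to 2.41%) against 7.33% (6.85% to 7.83%). Smooth muscle-like cells were 4.88% (4.42% to 5.38%) against 1.23% (1.03% to 1.45%), and plasma cell-like cells 0 of 7865, which allows a share of up to 0.0381%, against 0.162%. In club epithelial-like cells 114 genes were at least 4-fold higher in the PrPUr library and 77 in the glandular one. They included KRT13, a keratin of stratified mucosa (1605 CPM against 1.55), SPRR3, a cornified envelope precursor (at least 206-fold), UPK1B, a uroplakin of the urothelium (at least 144-fold), and CLCA4, a chloride channel regulator (149 CPM against 1.45), all higher in the PrPUr library. Among the other classes, each was highest in hillock epithelial-like cells, though below the limit for free-RNA-prone genes. Hillock-like cells or transcripts within the club epithelial-like class were not told apart from a difference of club-like cells. KRT13 was also higher in vascular endothelial-like cells (208 UMIs against 1), where it was free-RNA-prone. In fibroblast-like cells C1QTNF3 (8.41-fold) and PI16 (6.42-fold) were higher, and FABP5, a fatty acid carrier, was 4.78-fold higher in the glandular library. In myeloid-like cells MARCO, a scavenger receptor, was 8.45-fold higher in the PrPUr library, and the metallothioneins MT1H (at least 158-fold) and MT1G (30.4-fold) and the alarmin S100A8 (12.8-fold) were higher in the glandular one, of which MT1G was free-RNA-prone. In mast cell-like cells JUN (5.37-fold) and HSPA6 (4.25-fold) were higher in the glandular library. With 1 library each, these differences cannot be set against the spread between donors.

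**Figure D4:**
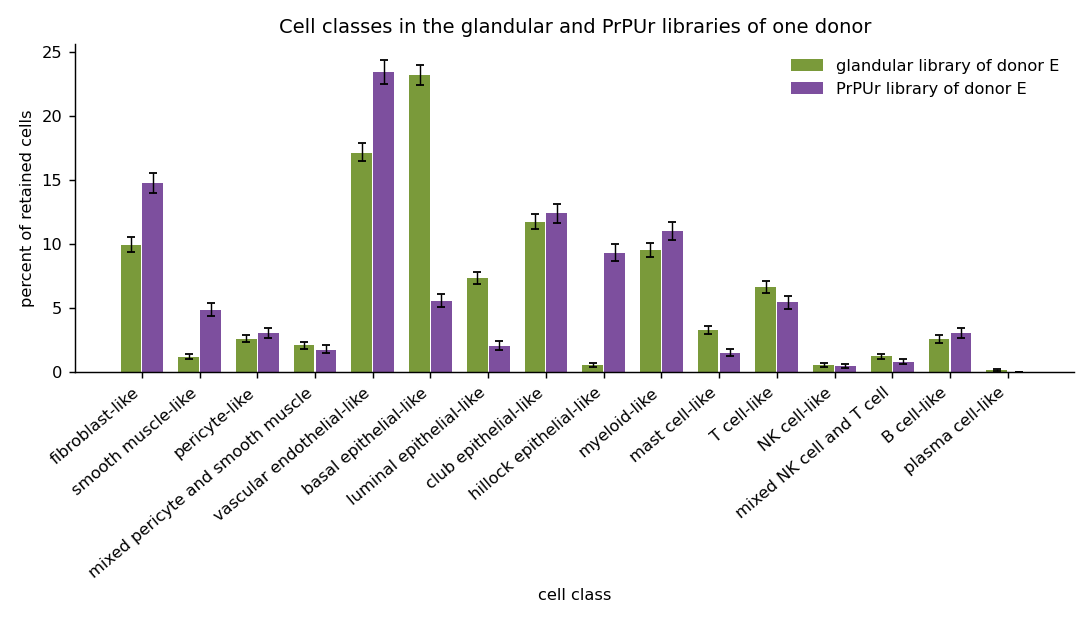
Bars give the percent of retained cells (vertical axis) in each cell class (horizontal axis) in the glandular and the PrPUr library of donor E, with exact 95% binomial intervals that cover counting error only. Hillock epithelial-like cells were 9.33% of the PrPUr library and 0.557% of the glandular library.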

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

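In this part, the tests of free RNA and of a single kit as the source of the metallothionein difference were chosen after the result had been seen, and the others before.

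Luminal and basal transcripts were lower in the stromal samples in cell classes that should not make them, with called log2 fold changes of -4.10 to -3.0 for MSMB in 9 classes and -3.50 to -2.31 for KRT14 in 9 classes. Fibroblast and vessel transcripts were higher in immune classes, such as DCN in myeloid-like cells (1.87). Free RNA in the droplets may account for this pattern. Called free-RNA-prone genes mostly moved the way their share moved in all other cells of the same samples. Counted per gene and class, 94.8% did (201 of 212, exact 95% interval 90.9% to 97.4%). Of the other called genes, counted likewise, 61.1% did (173 of 283). Genes such as MSMB recur in several classes of the same samples, so these counts are not independent and the interval is too narrow. For cells captured together, the 1% of cells with the most UMIs of a luminal secretory gene held a median of 19.4% of that gene's UMIs. The range was 3.85% to 78.4% over 106 combinations, 8 of them at 50% or more. Such cells could be spread over more than 1% of a class, since 2.42% to 12.8% doublets were expected per library. The median therefore does not exclude them. A difference between the specimen types within these classes stays open for the prone genes and was not tested apart from free RNA.

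The metallothionein list, which includes MT1A, was lower in stromal samples in 7 classes, from a median of -0.63 in fibroblast-like to -1.86 in club epithelial-like cells at the preset correlation. With an estimated correlation, adjusted p ranged from 0.156 to 0.279. Without free-RNA-prone genes, 100% of the camera calls tested again held at the preset correlation (5 of 5, highest adjusted p = 0.00118). These were in fibroblast-like, smooth muscle-like, pericyte-like, basal epithelial-like and club epithelial-like cells. Free RNA stays open as a source there, since members higher in another class but below the limit for prone genes were kept. In myeloid-like and T cell-like cells free RNA cannot be told apart from a difference within the class, since 2 members other than MT1A were not prone, both in T cell-like cells, too few to test the list again. Donors of a single kit cannot be told apart either, because kit version 3 had 2 pairs. Without MT1A, 95.2% of the medians per class and donor lay below 0 with version 2 (20 of 21, -2.69 to 0.0870) and 100% with version 3 (12 of 12, -3.43 to -0.230). The 7 classes were those called lower over the same donors, so mostly negative medians follow in part from that choice. Classes of a donor are not independent either. Reads shared between the near-identical copies remain open for single members and were not tested. A difference between specimen types could remain, and so could a difference in handling, because metallothioneins respond to metals and stress.

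The glandular libraries F1 and F2 of donor F differed in epithelial-like cells, with 38.0% (exact 95% interval 36.8% to 39.3%) and 7.0% (6.41% to 7.63%). Depth per cell is argued against, since cells of at least 1500 UMIs gave 39.6% and 6.70%, a ratio of 5.91. Filters on cells cannot be told apart from a difference of the tissue, because with every barcode kept the basal markers' share of UMIs was 0.183% and 0.0959%, a ratio of 1.90 that lay between the bounds of 1.5 and 2 set beforehand. Different pieces of tissue are a candidate explanation that no value here tests.

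Of 468 groups of 4 or 5 samples examined for a value far from the rest, 25 held one, and chance gives about 1 in 20 groups. The numbers in parentheses below are the gap to the nearest sample divided by the range of the group. Among shares, the hillock epithelial-like share was 8.49% in glandular A with 2.89% next (0.681), the epithelial share 29.9% in stromal C with 6.57% next (0.80), and the basal epithelial-like share 26.4% in stromal C with 5.28% next (0.801). The myeloid-like share was 21.6% in stromal B with 12.5% next (0.736), the pericyte-like share 15.1% in stromal F with 5.15% next (0.856), and the share of unnamed cells 31.4% in stromal A with 0.734% next (0.984). In pericyte-like cells of glandular samples, NTRK2 (0.785) and CPED1 (0.896) were low in donor C, each at a single UMI, and PDE8B (0.889) was low in donor B. In pericyte-like cells of stromal samples, SELE was low (0.721) and LUM high (0.815) in donor C, and CYP1B1 (0.713) and EGFL6 (0.758) were low in donor F. CXCL12 was high in endothelial-like cells of glandular C (0.729), KRT18 low in those of stromal F (0.744), and MIR205HG high in fibroblast-like cells of stromal C (0.71). MT1G was high in basal epithelial-like cells of glandular A (0.852), KLK3 in those of glandular D (0.891), and CCL18 in myeloid-like cells of glandular D (0.753). In mast cell-like cells, IL13 was low in glandular B (0.728), DUSP4 high in stromal D (0.836), and ANXA1 low in stromal A (0.802). CSF3 (0.720) and SELE (0.735) were low in T cell-like cells of stromal C, each at a single UMI, and ZFAND2A was high in NK cell-like cells of stromal B (0.837).

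The specimen effect differed between the kits by an interaction test in 1 gene in fibroblast-like cells, 2 in smooth muscle-like, 7 in vascular endothelial-like, 1 in myeloid-like, 2 in mast cell-like, 1 in NK cell-like and 22 in B cell-like cells. It also differed for the hillock epithelial-like share, by 6.65 on the log2 scale (mean log2 ratio -5.43 with kit version 2 and 1.25 with version 3, adjusted p = 0.00797). Within the epithelial lineage the hillock epithelial-like share was lower in each stromal sample of kit version 2 (mean -9.51 points) and higher in each of version 3 (65.1 points), a difference of 74.6 points that was not tested. The stromal samples of version 3 held few epithelial-like cells, 247 in donor D and 61 in donor F. Of these, 109 and 55 were hillock epithelial-like, which was 0.777% and 0.644% of all cells there.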

How the results depend on the processing

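Leaving out unnamed cells or cells under 1500 UMIs and using F1 or F2 alone were chosen after the results had been seen, and the other alternatives before. The epithelial share of cells stayed lower in stromal samples in all 16 alternatives (-43.3 to -16.3 points). Without the donor block, with the glandular sample of donor E added, it passed an exact unpaired permutation test (-32.9 points, exact permutation p = 0.0216). That test ignores the pairing and is not the paired sign-flip test, which cannot pass with 5 pairs. The 3 called shares were 5 with doublets kept, 1 with an ordinary graph, 1 without the block, 0 in the sign-flip test and 0 to 4 with a donor left out. Of 3520 values of named genes under the alternatives, 2484 kept their direction and their side of the threshold, 1011 no longer passed, 22 newly passed and 3 changed direction. These 3 were C7 in fibroblast-like cells (0.00177 with doublets kept, 0.0546 in kit 2 pairs, and -0.143 to 0.0593 with a donor left out). DESeq2's size factors kept 208 of 212. Below, called genes are given in the order fibroblast, smooth muscle, pericyte, endothelial, basal, club, myeloid, mast, T, NK and B cell-like, for the classes that moved over 1.5-fold. Leaving out a donor gave 18 to 244, 14 to 46, 21 to 114, 5 to 85, 4 to 32, 0 to 35, 17 to 81, 16 to 72, 23 to 183, 1 to 41 and 5 to 31. No filter on low counts gave 658, 134, 412, 262, 201, 73, 657, 114, 459, 46 and 118. The no-block fit gave 1 in fibroblast-like, 1 in mast cell-like and 0 in the other classes, and with kit as a covariate 8 in fibroblast-like, 1 in mast cell-like, 3 in T cell-like, 1 in NK cell-like, 5 in B cell-like and 0 in the others. Kit 2 pairs gave 13, 6, 27, 44, 4 (basal), 35 (club), 16 (myeloid), 17 (mast), 36 (T) and 50 (B). Doublets kept gave 60 (smooth muscle), 18 (basal) and 21 (NK), a 10% mitochondrial ceiling 42 (myeloid), doubled resolution 80 (smooth muscle), and an ordinary graph 8 (smooth muscle) and 17 (basal). DESeq2 gave 49 (endothelial), 42 (basal), 10 (club), 131 (myeloid), 21 (mast) and 8 (NK), a 50-cell minimum 4 (basal) and 72 (mast), and at least 1500 UMIs 66 (T) and 5 (NK). Without free-RNA-prone genes 3 (endothelial), 1 (basal), 9 (myeloid), 3 (NK) and 0 (B) stayed, by fewer genes tested. The 109 list calls were 38 without prone genes, where androgen response turned in fibroblast-like (adjusted p = 0.191), endothelial-like (0.435) and mast cell-like cells (0.647) and chemokines in basal (0.0126) and mast cell-like cells (0.284). They were 0 with an estimated correlation, and dissociation stress in B cell-like cells turned without the block (adjusted p = 0.608). Values that did not pass also changed direction. The share of mixed pericyte and smooth muscle cells was -0.244 with a 10% mitochondrial ceiling and -0.0499 to 0.704 with a donor left out, and the share of mixed NK cell and T cell clusters 0.247 without the block and -0.969 to 0.0397. The share within lineage of smooth muscle-like cells was 1.47 points with an ordinary graph. With a donor left out, the share of T cell-like (-0.189 to 0.393), the share of myeloid-like (-0.232 to 0.495) and the share of mast cell-like cells (-0.231 to 0.471) crossed 0. So did, in points, the share within lineage of vascular endothelial-like (-0.499 to 6.81), the share within lineage of club epithelial-like (-5.06 to 1.05) and the share within lineage of basal epithelial-like cells (-21.4 to 2.85). Except where fewer genes or donors were tested, the cause was not tested. Depth limits rare classes, such as NK cell-like samples of 88620 UMIs, where low transcripts could not be tested.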

Other observations

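The size of the T cell clusters was chosen for a test after it had been seen, and the splits of the samples before.

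T cell-like cells fell into 2 clusters. Cluster 7 was led by GZMK, a granzyme, CCL5, a chemokine, IFNG, the type II interferon, NKG7 and CD8A, a receptor of cytotoxic T cells. Cluster 8 was led by IL7R, the interleukin-7 receptor, KLRB1 and LTB, a lymphotoxin. Cluster 7 held 38.9% ± 14.1 of the T cell-like cells in glandular and 67.0% ± 15.7 in stromal samples (SD, n = 5 donors), a difference of 28.2 points ± 12.8. It was higher in 5 of 5 stromal samples, by 28.8 points with kit version 2 and 27.3 with version 3. A candidate explanation is that specimen type goes with the make-up of the T cells, but the exact two-sided sign-flip p = 0.063 is the smallest that 5 pairs allow, so the test cannot tell.

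Other splits of the same samples, with the donor block kept, were used to ask whether chance can be excluded. Over all splits drawn, under 5% gave at least as many genes as the real one in fibroblast-like (111 called, 3 of 100 splits, highest other 180), smooth muscle-like (33, 3 of 100, highest other 35), and pericyte-like cells (83, 1 of 100, highest other 37). The same was seen in myeloid-like (67, 3 of 100, highest other 93), mast cell-like (33, 4 of 100, highest other 51), T cell-like (118, 1 of 100, highest other 36) and B cell-like cells (19, 3 of 100, highest other 23). For the class shares (3, 3 of 100, highest other 3) and the lists in classes with 5 pairs (87, 2 of 100, highest other 87) the share was also under 5%. It was 5% or more, so that chance was not excluded, in vascular endothelial-like (18, 7 of 100, highest other 49), basal epithelial-like (9, 5 of 32, highest other 53) and NK cell-like cells (13, 3 of 32, highest other 20). In club epithelial-like cells the real count was 0, which fixes the outcome (32 of 32, highest other 19), so nothing was tested there. The 53 genes of a basal epithelial-like split and the 49 of an endothelial-like split, several times the real counts, point to a structure of the samples that was not tested. Most of these splits put both samples of some donors on the same side, unlike the real one. Those that part every donor pair (12 drawn, or 8 with 4 pairs) are too few for a share under 5%, so the counts over all splits do not settle chance for the paired comparison. Among them the highest others were 34 in fibroblast-like, 1 in smooth muscle-like, 12 in pericyte-like, and 5 in endothelial-like cells. They were 3 in basal epithelial-like, 19 in club epithelial-like, 4 in myeloid-like, 51 in mast cell-like, 32 in T cell-like, 0 in NK cell-like and 7 in B cell-like cells. Those for shares and lists were 1 and 76. In mast cell-like cells 2 of the 12, the real one included, gave at least as many genes as the real one.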
